A study of Mus musculus with 2 samples.

How the data were processed

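The samples were 2 preparations of mouse bone marrow-derived macrophages, 1 labelled c-Maf+/- and 1 labelled c-Maf-/-, treated with 100 ng/ml LPS for 5 h after 5 days in M-CSF. Per the labels' protocols, 50 ng of total RNA was labelled with Cy3 for each array. The deposited values are spot intensities written by Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09 for array design 028005, per the file headers. Each array had 62976 spots, 59305 of them not controls, which held 55681 probes. Per the file headers, the processed signal was background-subtracted with spatial detrending within the array, with surrogate values for low spots, and was not normalized between arrays. The other columns used were the deposited mean and background median intensities and the 0 and 1 flags for outliers, saturation and detection. Both arrays were on 1 slide, so slide and genotype were not confounded, but a position on the slide belongs to 1 genotype only.

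The log2 scale was computed here, since the deposited intensities are linear. From log2 of each processed signal, that array's value at the 75th percentile of the non-control spots was subtracted (signals of 291 for c-Maf+/- and 296 for c-Maf-/-). Spots flagged as outliers (136 and 149) were dropped, saturated spots would have been kept but there were 0, and spots of a probe were averaged. A gene's value was the mean over its probes flagged as well above background on both arrays. A gene well above background on 1 array only was given a bound, the brighter value against the higher of the lowest signal well above background on the dim array (22.3 for c-Maf+/- and 24.2 for c-Maf-/-) and the dim probe's own signal. Low signals near background limit the precision of dim genes, and the number of arrays limits every comparison.

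Gene names came from the deposited probe annotation, updated through a table of RefSeq genes by accession (28020 probes), symbol (3198), another accession (321) or an older symbol (272). A further 23870 probes had no match and kept the name in the files, and counts cover matched names only. Outside them, 4745 other names were measured on both arrays, with 58 at least 2-fold higher and 41 lower. Probe coordinates are those of the files, build mm9. An annotation of that build was not used here, so exon and UTR positions are not stated. The reference table was of another build and gave names and no coordinates.

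With 1 array per genotype no test of the genotypes was possible, and no p-value was computed for any gene. Genes were counted at 2-fold in each direction. For each of 27 gene lists the median log2 difference was placed among 10000 random lists of the same size, matched on 10 bins of mean signal, for lists with at least 5 measured genes. A list was outside the random range when it lay in the outer 2.5% of random lists at either end. The share of random lists as extreme was adjusted over lists by Benjamini-Hochberg. That share is a permutation p-value over genes, not over samples, and describes these 2 arrays only. The groups, gene lists, 2-fold threshold, alternatives and rule for named genes were fixed before the data were examined. The rule takes Maf, the 12 genes with the largest difference each way that have an official symbol and probes of 1 sign, the 4 largest bounds each way among such symbols (clone, predicted and numbered names are left out), and the 4 members of each list farthest from 0. It adds Il10, Il12b, Il6, Tnf, Il1b, Csf1r and Myc whatever their value, and list members past 2-fold. A few genes the rule takes are not reported here. C1qb, C1qc, Ccl2, Ccl5, Nos2, Acod1 and Ptgs2 were added after their values were seen.

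The lists were Maf family and partner factors, inflammatory cytokines, IL-10 and anti-inflammatory genes, chemokines, interferon-stimulated genes, NF-kB feedback genes, nitric oxide, prostaglandin and immunometabolic genes, resident-type macrophage genes, alternative activation genes, self-renewal network genes, cell cycle genes and pan-macrophage identity genes. Further lists were antigen presentation and co-stimulation, scavenging, efferocytosis and complement genes, antioxidant genes, ER stress and stress-response genes, genes near Maf, reference genes and sex-linked genes. Markers covered neutrophils, dendritic cells, monocytes and progenitors, lymphocytes, mast cells and basophils, erythroid cells and megakaryocytes, stroma and endothelium, and osteoclasts.

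Precision was read from 215 probes with at least 8 usable spots, whose log2 differences had a median SD of 0.07 (95th percentile 0.23), and from 3451 genes with at least 2 probes (median SD 0.09, 95th percentile 0.48). The 8 spike-in transcripts differed by a mean of -0.14 (SD 0.03). On simulated data with the noise between probes and 200 of 12416 genes changed, the 2-fold threshold called 98.5% of genes changed 2.5-fold, 100% of those changed 4-fold, 0% of those changed 1.5-fold and 0 of 12216 unchanged genes. Of 200 simulated lists of 20 unchanged genes, 3% lay outside the percentile range, against 100% when 75% of their genes were shifted by 0.3. This noise is that of the array and holds no spread between cultures. Every probe was given the same noise, the median SD of 0.09, although the 95th percentile was 0.48. The simulation therefore gives no error rate for dim or noisier genes, or for lists of genes that vary together.

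Alternatives were normexp background correction with an offset of 50, no background subtraction, quantile and cyclic loess normalization, scaling on probes well above background on both arrays, no filter or a stricter filter on dim probes, and keeping outlier spots or dropping saturated ones. Others were the brightest probe per gene, thresholds of 1.5-fold and 3-fold, unmatched random lists, lists without their most extreme member, another floor and another detection flag. Scaling on spike-ins, a limit to genes with at least 2 probes and 3 further gene lists were added after the data were seen. Normexp, quantile and loess used limma 3.58.1 in R 4.3.3, and other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Plots were drawn with matplotlib 3.10.9.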

Results

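Gene expression was measured in mouse bone marrow-derived macrophages, which are macrophages grown from marrow progenitors, that either kept 1 working copy of the c-Maf gene (c-Maf+/-) or had none (c-Maf-/-). Marrow had been cultured for 5 days with M-CSF, the growth factor that drives macrophage differentiation, and the cells were then treated for 5 h with 100 ng/ml lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4. c-Maf, encoded by Maf, is a basic leucine zipper transcription factor known for driving Il10 in macrophages. Each genotype was measured on 1 one-colour array, and both arrays were on the same slide. There was thus no replicate of either genotype, no test of the genotypes was possible, and every difference below is between these 2 arrays. Of 59305 non-control spots, 45.3% were well above background on the c-Maf+/- array and 44.9% on the c-Maf-/- array, and no spot was saturated. The only question the design poses is which transcripts differ between LPS-treated macrophages without c-Maf and those with 1 copy. All log2 differences are c-Maf-/- minus c-Maf+/-.

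Maf itself was bright in c-Maf+/- macrophages and not well above background in c-Maf-/- macrophages. The brighter of its 2 probes (chromosome 8, 118227736 to 118227795, mouse build mm9) had a signal of 15101 in c-Maf+/- and 12.6 in c-Maf-/-, which makes it at least 636-fold lower. The other probe (chromosome 8, 118207273 to 118207332) had signals of 541 and 5.96, at least 22.8-fold lower, and with both probes averaged Maf was at least 120-fold lower, a log2 bound of -6.91 that was -4.97 with normexp background correction and -5.29 without background subtraction. The labels do not say which part of the gene was deleted, so whether the probes lie inside it was not settled. Both probes go with the genotype labels. Of the genes around Maf on chromosome 8, 12 were measured, with a median log2 difference of 0.08, at percentile 91.7 of matched random lists. Among these neighbours Nudt7 (0.97) and Atmin (0.75) were higher and Cdyl2 (-0.44) and Gcsh (-0.36) lower in c-Maf-/-.

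Beyond Maf, the largest differences among genes with an official symbol measured on both arrays were lower Ccl8 and Fgl2 and higher Scd2 in c-Maf-/- macrophages. Ccl8, a chemokine that attracts monocytes, was 11.8-fold lower (log2 difference -3.56), and Fgl2, a fibrinogen-like prothrombinase, was 10.8-fold lower (-3.43). Also among the 12 lowest were the collagenase gene Mmp13 (-2.58), carbonic anhydrase 2 (Car2, -2.29), calponin 3 (Cnn3, -2.24 over 2 probes), the eotaxin receptor gene Ccr3 (-2.18), Il10 (-2.17) and the mannose receptor gene Mrc1 (-2.14). Scd2, a stearoyl-CoA desaturase of fatty acid synthesis, was 13.6-fold higher (3.76), and its relative Scd1 was 4.43-fold higher (2.15). Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, and the angiogenic factor gene Vegfa were each higher by 2.49 over 2 probes. The protease inhibitor gene Slpi was higher by 2.40, from a signal of 10064 to 53910. Apart from Cnn3, Egln3 and Vegfa, each gene named in this paragraph rested on 1 probe. Scd1 was also dim in c-Maf+/-, at a signal of 31.7.

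The remaining genes among the 12 at either end were Sly (-2.69), Rasgef1a (-2.32), Mab21l3 (-2.28) and Meikin (-2.27) on the lower side. On the higher side they were Wdr11 (2.63), Rhbdd2 (2.57), Smad6 (2.23), Abi3 (2.16), Cxcl5 (2.11), Erdr1 (2.07) and Mgarp (2.07). Most of these were dim on the lower array, as with Rhbdd2 at a signal of 26.4 and Rasgef1a at 32.2, and each rested on 1 probe. Sly belongs to a Y-linked family of near-identical copies, so its probe may read relatives, and its difference was -0.28 when dim probes were kept. Some genes with an official symbol had matched probes well above background on 1 array only. Of these, the largest bounds on the c-Maf+/- array after Maf were Col13a1 (at least 7.79-fold), Xist (7.33 over 2 matched probes) and Col12a1 (6.13). On the c-Maf-/- array they were Oosp2, Csnka2ip, Nkd1 and Eda, each from a single probe, with bounds from at least 10.2-fold for Eda to at least 10.9-fold for Oosp2.

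**Figure D1:**
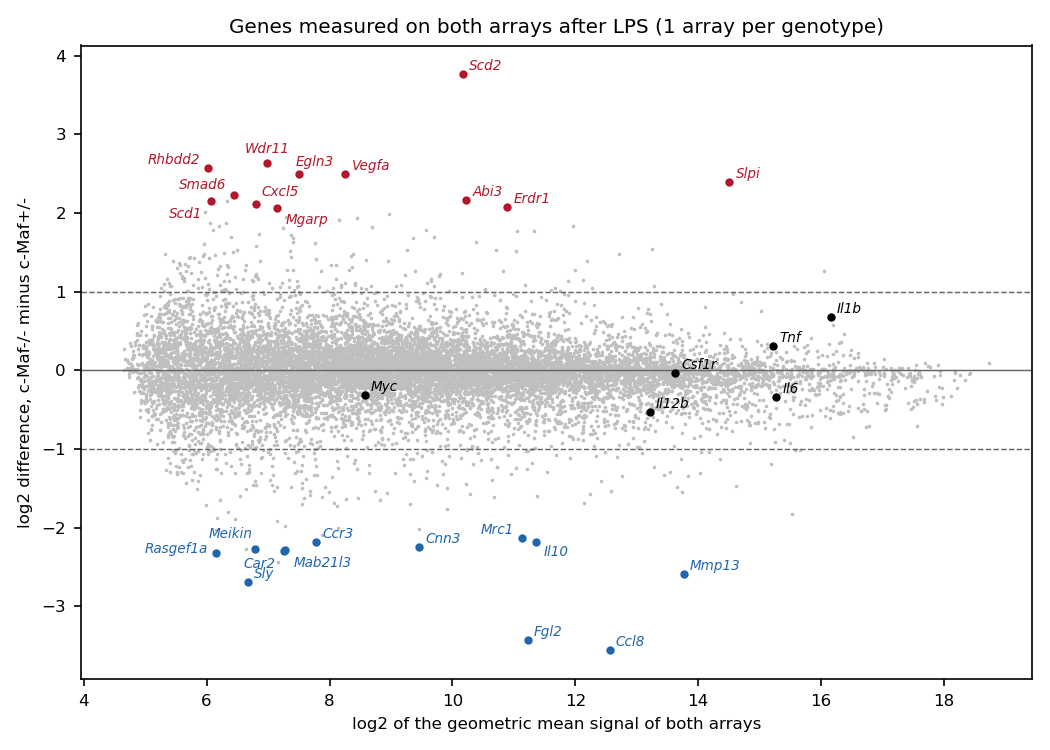
Log2 difference between the arrays (c-Maf-/- minus c-Maf+/-) against the log2 geometric mean signal, 1 point per gene measured on both arrays (12416 genes, 1 array per genotype). Blue and red mark the 12 genes at each end of the named-gene rule, black marks other preselected genes, dashed lines lie at 2-fold, and Ccl8 (-3.56) and Scd2 (3.76) lie farthest from 0.

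Across the 12416 genes measured on both arrays, 177 were at least 2-fold higher and 216 at least 2-fold lower in c-Maf-/- macrophages. These counts were 68 and 109 with normexp, 82 and 124 without background subtraction, and 885 and 871 without the filter on dim probes. The log2 differences had a median of -0.02 and an SD of 0.41, and 96.8% of genes lay within 2-fold. Of the calls, 45.0% were on the higher side. Scaling on the spike-in transcripts instead moved the median of all genes, and each list median, by 0.14 and this share to 64.9% (262 higher, 142 lower), so directions close to 0 depend on the scaling and list medians are best read against the other genes. Spots of 1 probe differed with a median SD of 0.07, and probes of 1 gene with a median SD of 0.09. These spreads cover the array alone, not cultures or mice. All probes went the same way in each of the 49 multi-probe genes past 2-fold. These genes were picked on the mean of the same probes, so a shared direction was close to fixed in advance. The other genes past 2-fold rested on 1 measured probe.

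Il10 and genes of the anti-inflammatory response were lower in c-Maf-/- macrophages. Il10, which encodes the main cytokine that restrains macrophage activation, had a signal of 5521 in c-Maf+/- and 1245 in c-Maf-/-, 4.51-fold lower, with an SD of 0.06 over 10 spots of its probe (chromosome 1, 132920943 to 132921002, mm9). Of 20 measured genes in the list of IL-10 and anti-inflammatory genes, 16 had a value below 0, 4 of them at least 2-fold, and none was 2-fold higher. Besides Il10, those 4 were Mertk (-1.91), a receptor for apoptotic cells, its ligand gene Gas6 (-1.35), and Il4ra (-1.69), the interleukin-4 receptor alpha chain. Mertk, Gas6 and Il4ra also belong to other lists below. The median of this list was -0.32, at percentile 0 of 10000 random lists matched on signal. Hmox1, heme oxygenase 1, went the other way in this list (0.86). Markers of neutrophils and dendritic cells were also lower (medians -0.63 and -0.71).

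Inflammatory cytokine genes did not go 1 way. Il1b was higher in c-Maf-/- macrophages by 0.68 (SD 0.05 over 9 spots) and Tnf by 0.31 (SD 0.03 over 9 spots), while Il12b was lower by a log2 difference of -0.53 (SD 0.05 over 10 spots) and Il6 by -0.34. The only member past 2-fold was Il15 (-1.24), a cytokine that sustains natural killer cells, followed by Ifnb1 (-0.95), which encodes interferon beta, and Il27 (-0.86). The median over 17 measured genes was -0.09 (percentile 17.0), and it turned to 0.04 with spike-in scaling. At this time after LPS, Tnf and Il6 were bright in both genotypes, with Tnf signals of 33968 and 42963.

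Chemokine genes went both ways. The neutrophil-attracting chemokine genes Cxcl5 (2.11), Cxcl1 (1.99), Cxcl3 (1.77) and Cxcl2 (1.14) were the 4 members at least 2-fold higher in c-Maf-/- macrophages. The 4 members at least 2-fold lower were the monocyte attractants Ccl8 (-3.56) and Ccl12 (-1.83), the interferon-inducible Cxcl9 (-1.40), and Cx3cl1 (-1.26). Ccl12 went from a signal of 88509 to 25351, while Cxcl3 went from 1370 to 4770. The remaining 15 of 23 measured chemokine genes lay within 2-fold, among them the monocyte attractant Ccl2 (-0.12) and Ccl5 (-0.06). The list's median of -0.13 (percentile 6.38) turned to 0.01 with spike-in scaling. The Cxcl1, Cxcl2, Cxcl3 and Cxcl5 values were above 1 under every scaling, but each alternative scaling shifted differences upward, so this does not test the scaling.

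Interferon-stimulated genes were lower in c-Maf-/- macrophages as a group, by a small amount. All 45 measured members had a value below 0 with the main, quantile and loess scalings, and 42 with spike-in scaling. The median was -0.32 (percentile 0), and 2 members were past 2-fold, the GTPase gene Iigp1 (-1.53 over 2 probes) and Ifit2 (-1.02). Ifit2 lay just within 2-fold under each of the 4 alternative scalings, at -0.88 with spike-in scaling. Next came Irf1 (-0.99), a transcription factor of the interferon response, and Ifit1 (-0.92). Feedback genes of NF-kB, the transcription factor family activated by LPS, had a median of -0.22 (percentile 0.02), with 20 of 27 below 0. Nfkbiz (-1.20) and Cd83 (-1.05) were the 2 past 2-fold, although Cd83 was at -0.99 with quantile normalization and -0.91 with spike-in scaling, and Rel (-0.97) and Ripk2 (-0.91) came next. With genes of at least 2 probes only, the NF-kB median was -0.17, at percentile 7.46, inside the random range.

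Genes typical of resident tissue macrophages were lower in c-Maf-/- macrophages, with a median of -0.63 over 26 measured genes (percentile 0). Mrc1 (-2.14), the carbonyl reductase gene Cbr2 (3.99-fold lower), Mertk (-1.91), the folate receptor gene Folr2 (-1.57), the iron exporter gene Slc40a1 (-1.41), Fcrls (-1.38) and Gas6 (-1.35) were at least 2-fold lower. The complement genes C1qb (-0.74) and C1qc (-0.81) lay within 2-fold. The ectoenzyme gene Cd38 (1.69) and the scavenger receptor gene Marco (1.01) were at least 2-fold higher. With normexp background correction Slc40a1 (-0.77) and Marco (0.99) lay within 2-fold. Scavenging, efferocytosis and complement genes, of which 11 of 30 are shared with other lists, had a median of -0.31 over 27 genes (percentile 0.01). Mertk, Gas6 and Marco were again past 2-fold there, and C3ar1 (-0.94), a complement receptor gene, came next. With genes of at least 2 probes only, this list's median of -0.15 lay at percentile 9.66, inside the random range.

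Genes of alternative activation, the state macrophages enter with interleukin-4, had a median of -0.38 over 18 genes (percentile 0.01) but went both ways. Mrc1 and Il4ra were at least 2-fold lower, whereas Arg1 (1.95), the arginase gene, and the ribonuclease gene Ear2 (1.11, but 0.76 with normexp) were at least 2-fold higher. Pan-macrophage identity genes had a median of -0.09 over 30 genes (percentile 15.8), which turned to 0.04 with spike-in scaling and 0.01 with quantile normalization. Csf1r, the M-CSF receptor gene, was at -0.03 over 3 probes, Aif1 at -0.61, Tlr4 at -0.61 and Lyz2 at 0.58. Cebpa (1.11, but 0.76 with normexp) was the only one of these 30 past 2-fold. Antigen presentation and co-stimulation genes had a median of -0.06 over 20 genes (percentile 38.4), which turned to 0.08 with spike-in scaling. Within it Cd86 was at -0.77, Cd40 at -0.59, Cd80 at 0.48 and H2-Ob at 0.35.

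Genes of oxidative defence were higher in c-Maf-/- macrophages, and stress genes leaned the same way less evenly. The antioxidant list, made of genes known as targets of NRF2, had a median of 0.22 over 19 genes (percentile 100), with 16 above 0. Slc7a11 (1.40), the cystine importer gene, and Osgin1 (1.24) were past 2-fold, followed by Hmox1 (0.86) and Srxn1 (0.84). The nitric oxide, prostaglandin and immunometabolic list had a median of 0.13 over 23 genes (percentile 99.98), with Vegfa (2.49), Arg1 (1.95) and Alox5 (1.08, but 0.98 with normexp) past 2-fold and the glucose transporter gene Slc2a1 at 0.75. Its LPS-inducible enzymes Nos2 (-0.20), Acod1 (-0.01) and Ptgs2 (-0.19) lay close to 0. With the brightest probe per gene this list's median was 0.08 (percentile 99.83), and with genes of at least 2 probes the antioxidant median was 0.13 (percentile 99.08). ER stress and stress-response genes had a median of 0.16 over 23 genes (percentile 99.98), with 15 above 0, 8 below 0 and none past 2-fold. Trib3 (0.94), Sesn2 (0.94) and Hsph1 (0.89) were highest and Egr1 (-0.88) lowest.

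Other members of the Maf family and its partners had a median of 0.09 over 9 genes (percentile 90.0). Maff was higher in c-Maf-/- by 1.11 and Mafg by 0.68 over 4 probes, while the repressor gene Bach1 was lower (-1.07). Maff was within 2-fold with normexp (0.91) and Bach1 with spike-in scaling (-0.94). Self-renewal network genes, a set that includes Myc and Klf4, had a median of -0.16 over 13 genes (percentile 6.29). Mycl (-1.45, but -0.88 with normexp) was the only member past 2-fold, with Klf4 at -0.62, Id1 at -0.46, Smad3 at -0.42 and Myc at -0.31. Cell cycle genes had a median of -0.21 over 41 genes (percentile 0), none past 2-fold, with 31 below 0, led by Ccnd2 (-0.72), Pcna (-0.66), E2f8 (-0.58) and Mcm7 (-0.55). That median was -0.03 (percentile 45.6) with genes of at least 2 probes only.

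Markers of other cell types did not go the same way. Neutrophil markers had a median of -0.63 over 14 genes (percentile 0), with the granule genes Ngp (-1.45), Ltf (-1.41), Prtn3 (-1.31) and Mpo (-1.21), and S100a9 (-1.01), at least 2-fold lower in c-Maf-/-. With normexp Prtn3 (-0.72) and Mpo (-0.82) lay within 2-fold, as did S100a9 under each of the 4 alternative scalings (-0.87 with spike-ins). Dendritic cell markers had a median of -0.71 over 11 genes (percentile 0), with Fscn1 (-1.50), Itgax (-1.09) and Bcl11a (-1.06) past 2-fold and Batf3 at -0.89. The 2 probes of Bcl11a lay at -1.62 and -0.50, and it was within 2-fold under 5 settings (-0.55 with normexp), as was Itgax under 3 (-0.77 with normexp). The dendritic cell median was -0.26 (percentile 1.27) without the filter on dim probes. Erythroid and megakaryocyte markers, mostly dim, had a median of 0.65 over 11 genes (percentile 100), none past 2-fold, with Gp9 (0.91), Hba-a1 (0.83), Ppbp (0.79) and Slc4a1 (0.72) highest. That median was 0.31 with normexp, 0.40 without background subtraction and 0.26 (percentile 99.23) without the filter on dim probes. Monocyte and progenitor markers had a median of 0.04 over 12 genes (percentile 77.9), with Cx3cr1 (1.27 over 3 probes) and Ccr2 (1.03) higher, Cd34 (-1.21) lower and Ly6c1 at -0.46. Ccr2 was at 0.98 with normexp and Cd34 at -0.56 without the filter on dim probes.

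Stromal and endothelial markers had a median of -0.14 over 9 genes (percentile 13.5), with Dcn (-0.95), Col1a1 (-0.88), Kdr (-0.40) and Col1a2 (-0.32) farthest from 0. Without the filter on dim probes that median was -0.32, at percentile 0.45, outside the random range. The 2 probes of Kdr had opposite signs, at -0.95 and 0.15. Osteoclast markers also had a median of -0.14, over 12 genes (percentile 9.74), with Car2 (-2.29) past 2-fold, then Atp6v0d2 (-0.87), Tnfrsf11a (-0.85) and Dcstamp (-0.85). Lymphocyte markers had a median of -0.09 over 6 genes (percentile 26.0), which turned to 0.04 with spike-in scaling, with Lck at -0.94, Cd79b at 0.52, Cd79a at -0.33 and Cd3e at 0.19. Of the mast cell and basophil markers only Tpsb2 (-0.27), Hdc (-0.06) and Prss34 (0.02) were measured, with a median of -0.06. Reference genes had a median of -0.03 over 20 genes (percentile 65.8), all within 2-fold, which turned to 0.10 with spike-in scaling, 0.03 with quantile and 0.04 with loess normalization. Ywhaz (-0.23), Hprt (-0.21) and Pgk1 (0.21) were among the farthest from 0.

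**Figure D2:**
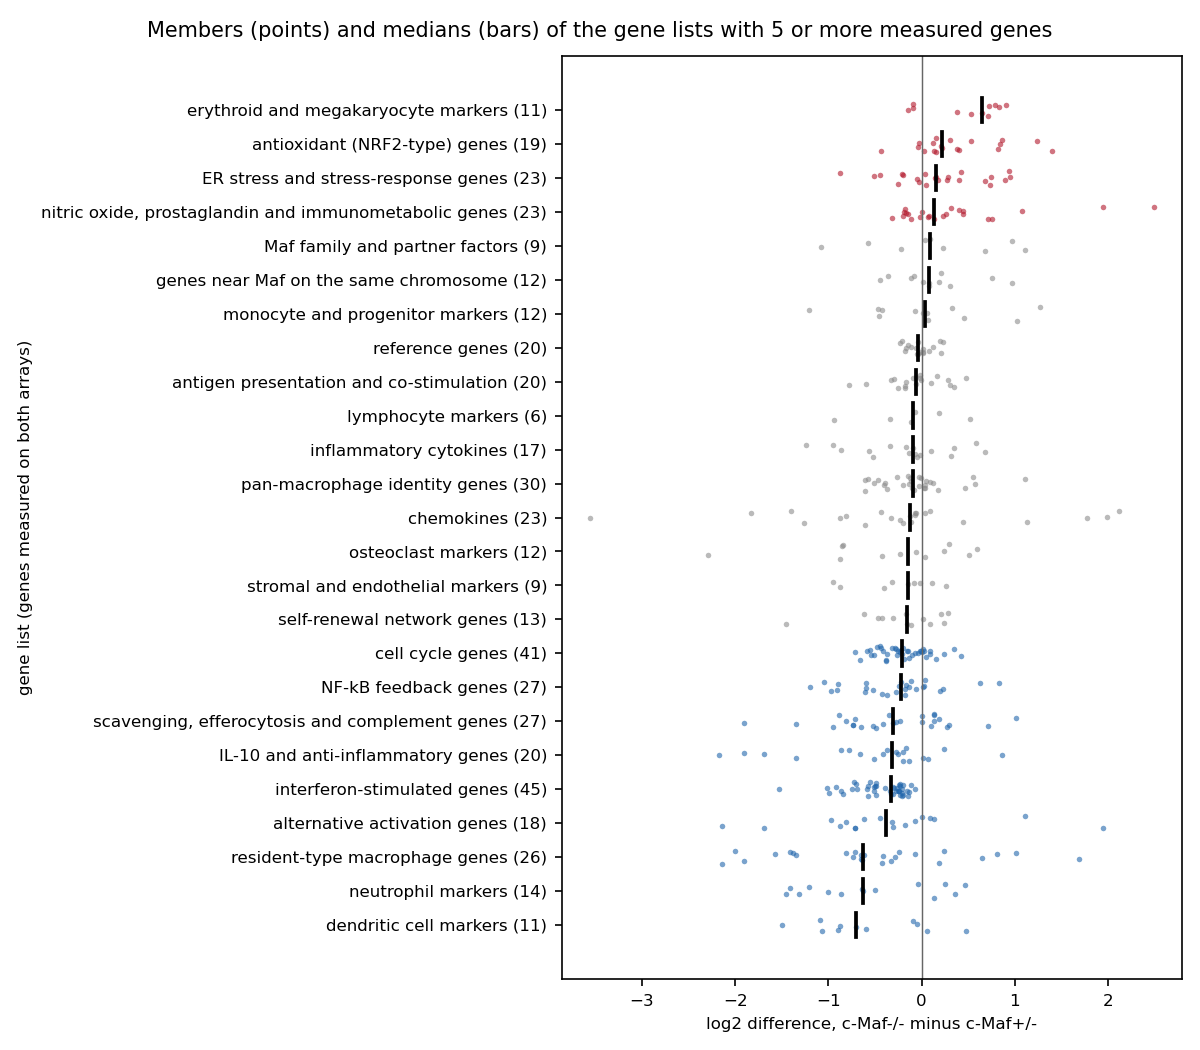
Log2 difference (c-Maf-/- minus c-Maf+/-) of each measured member (points) and the median (black bar) for the 25 gene lists with at least 5 genes measured on both arrays, whose number is given in parentheses. Red and blue lists lie in the outer 2.5% of matched random lists at either end, 4 on the higher and 9 on the lower side, and dendritic cell markers (-0.71) and erythroid and megakaryocyte markers (0.65) have the medians farthest from 0 on each side, which came nearer to 0 without the filter on dim probes (-0.26 and 0.26).

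Sex-linked transcripts differed between the arrays. Xist, the RNA that coats the inactive X chromosome of female cells, was well above background on the c-Maf+/- array. It was at least 7.33-fold lower on the c-Maf-/- array over the 2 probes matched to its symbol. Another 5 probes, named XIST in the files, had log2 differences from -6.62 to -3.27, and 2 of them were well above background on both arrays. The Y-linked genes Eif2s3y (0.64), Ddx3y (0.50) and Uty (0.23, over 2 probes) were measured on both arrays and were higher in c-Maf-/-, with a median of 0.50. The sex of the mice is not given in the labels used here, so genotype and sex are not separated in any comparison above.

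Of 25 lists with a percentile, 13 lay in the outer 2.5% of random lists at either end, and all 13 were under 0.05 after Benjamini-Hochberg adjustment of the share of random lists as extreme. The smallest such share that 10000 random lists can give is 0.0002. Some of these lists share members, so the 13 are not separate results. On another list too were 11 of 36 resident-type, 9 of 22 alternative activation, 11 of 30 scavenging and 4 of 20 IL-10 and anti-inflammatory genes. These percentiles describe the 2 arrays and not the genotypes, because genes of a pathway vary together and random genes do not. In addition, 467 genes were well above background on the c-Maf-/- array alone and 590 on the c-Maf+/- array alone. Their bounds reached 2-fold for 157 and 115 genes respectively.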

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

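The limits that picked these signals, a bound of at least 8-fold over at least 2 probes among names that matched no reference gene, were chosen after the results were seen, and no test was run on them. Such names enter no count of the main comparison. Most probes named for the immunoglobulin heavy chain variable family Igh-VJ558 were well above background on the c-Maf-/- array only, at least 17.6-fold higher over 3 of 4 probes, with mean signals of 4.96 in c-Maf+/- and 401 in c-Maf-/-. These 3 probes lie together on chromosome 12, between 114496985 and 114498407 (mm9), and the other lies apart at 116610609 to 116610667. The name is that of the files, and which part of the heavy chain locus the 3 probes read was not settled. The bounds of these 3 probes ran from 2.75-fold to 59.1-fold, and the other Igh-VJ558 probe was not well above background on either array (signals of 5.55 and 5.99). Jchain, the immunoglobulin joining chain gene, was likewise at least 7.58-fold higher in c-Maf-/-, while the B-cell receptor genes Cd79b and Cd79a were at 0.52 and -0.33. A transcribed region on chromosome 13, 81773237 to 81783062 on the reverse strand (mm9), was at least 8.36-fold higher in c-Maf-/- over 2 probes, with signals of 5.12 and 190.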

How the results depend on the processing

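Spike-in scaling and the limit to genes with at least 2 probes were chosen after the data were seen, and the other settings were planned. No paired analysis was possible because each genotype had 1 array and no test was made, and leaving out an array could not be run for the same reason. Maf was lower under each setting that gave a value. Its bound of -6.91 was -4.97 with normexp, -5.29 without background subtraction, -9.31 with the brightest probe and -6.77 with spike-in scaling, while the -8.39 without the filter on dim probes is a difference against signals at background and no bound. Counts of genes at least 2-fold higher and lower (177 and 216) were 68 and 109 with normexp, 82 and 124 without background subtraction, 885 and 871 without the filter on dim probes, and 49 and 87 in the upper range of signal. They were 17 and 32 among genes with at least 2 probes, 667 and 808 at 1.5-fold and 39 and 40 at 3-fold, where fewer or more genes could pass by construction. Spike-in scaling gave 262 and 142, because it adds 0.14 to every difference. Quantile (179 and 206) and loess (192 and 192) normalization stayed within 1.5 times. Genes well above background on 1 array only, 157 higher and 115 lower at 2-fold, were 84 and 54 with a floor at the 5th percentile and 497 and 423 with the positive and significant flag. List medians kept their side of the random range in 325 alternative values and left it in 4. Part of the 325 could not change. Scaling on spike-ins or on probes well above background adds the same constant to every gene, and 0 spots were saturated, so percentiles stayed as they were under those settings. Stromal and endothelial markers moved outside it without the filter on dim probes (-0.32, percentile 0.45). NF-kB feedback (-0.17, percentile 7.46), cell cycle (-0.033, percentile 45.6) and scavenging genes (-0.15, percentile 9.66) moved inside it with genes of at least 2 probes only, and the cause was not tested. Of 64 named genes past 2-fold, none reversed in 688 values. They were picked for large differences in these same data, and the scalings moved the median of all genes by at most 0.14. The lack of reversals was thus close to fixed in advance. Among the 64 genes, 18 came below 2-fold somewhere, in 40 values. Normexp accounted for Maff, Alox5, Slc40a1, Marco, Ear2, Mycl, Cebpa, Prtn3, Mpo, Itgax, Bcl11a and Ccr2, all but Mycl also without background subtraction. Spike-in scaling accounted for Bach1, Ifit2, Cd83, S100a9, Itgax and Bcl11a, with Ifit2 and S100a9 also under the other 3 scalings, and Sly and Cd34 came below without the filter on dim probes. Weak signal over background limits the dimmest genes, since 138 of the 177 higher and 143 of the 216 lower genes lay among the 6208 dimmest of 12416.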

Other observations

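The tests of explanations in this part, and its lists of hypoxia, proteolysis and lipid synthesis genes, were chosen after the results were seen. Hypoxia-responsive genes were higher in c-Maf-/- macrophages, with 28 of 32 measured genes above 0, a median of 0.49 (percentile 100) and 8 at least 2-fold higher. These were Egln3 (2.49), Vegfa (2.49), Mgarp (2.07), Ankrd37 (1.84), Ddit4 (1.77), Bnip3 (1.15 over 3 probes), Bhlhe40 (1.06) and Ak4 (1.04). Without Vegfa, Egln3, Ankrd37 and Mgarp, which prompted the list, the remaining 28 genes had a median of 0.41 (percentile 100). The list shares Vegfa, Slc2a1, Hk2, Ldha, Eno1, Pkm and Pfkfb3 with the nitric oxide, prostaglandin and immunometabolic list. The higher medians of these lists are thus not separate results. Genes of extracellular proteolysis went both ways, with a median of -0.16 over 20 genes (percentile 2.87). The collagenase gene Mmp13 (-2.58), Mmp10 (-1.51) and Mmp25 (-1.15) were lower and Slpi (2.40) was higher.

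Genes of fatty acid and sterol synthesis were higher in c-Maf-/- macrophages, with 25 of 28 above 0 and a median of 0.41. Scd2 (3.76), Scd1 (2.15), the sterol carrier gene Stard4 (1.34 over 2 probes) and the mevalonate pathway gene Mvd (1.08) were past 2-fold, and the squalene epoxidase gene Sqle was at 0.90. Their regulators Srebf1 and Srebf2 were at 0.27 and -0.16. The hypothesis that the whole group was higher was tested without Scd1 and Scd2, and the remaining 26 genes had a median of 0.41 at percentile 100. These data hold no second culture to test it on.

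Xist was far brighter on the c-Maf+/- array, with 2 of its 7 probes still well above background on the c-Maf-/- array, while Y-linked genes were on both. A defect of single spots is argued against, since 7 of 7 Xist probes were at least 2-fold brighter on the c-Maf+/- array, with signals from 115 to 1639 there against 5.43 to 43.7. Only female cells on that array is argued against too, because Eif2s3y had a signal of 2465 there, 110 times the lowest signal well above background. A mixture of male and female cells on the c-Maf+/- array may account for both, since the 3 Y-linked genes measured on both arrays had a median difference of 0.50. The female share needed differed by gene, if the c-Maf-/- array held only male cells and the scaling was exact. It was 29.2% for Ddx3y, 35.8% for Eif2s3y and 14.6% for Uty, a dim gene with probes at 0.09 and 0.37. Spike-in scaling adds 0.14 to each difference and would raise these shares. Whether pooled mice, a mixed litter or handling of RNA lies behind the Xist and Y-linked pattern stays open, as do an untested effect of genotype and the Y-linked Sly, lower in c-Maf-/- (-2.69) on 1 dim probe.

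The resident-type macrophage genes had a median of -0.63 in c-Maf-/-. The scalings tried moved the median of all genes by at most 0.14, so they could not bring this list to 0, and its median closest to 0 was -0.49. A shift shared by all genes is argued against as the whole cause, since the list lay at percentile 0 of random lists under each scaling. A lower share of macrophages as the whole cause is argued against only as far as the pan-macrophage genes are particular to macrophages. Their median lay 0.54 above the resident-type median (SD of the pan-macrophage genes 0.38). Markers of other cell types were not all raised. Neutrophil (-0.63) and dendritic cell markers (-0.71, or -0.26 without the filter on dim probes) were lower. Erythroid and megakaryocyte markers (0.65, or 0.26 without that filter) were higher. A stronger response to LPS could not be measured, since both arrays were LPS-treated and none was unstimulated. Levels after LPS were not higher across its gene groups. The interferon-stimulated median closest to 0 over the scalings was -0.19, while Cxcl1, Cxcl2, Cxcl3, Cxcl5 and Il1b were higher. An effect of c-Maf loss may account for the lower resident-type genes, as a hypothesis, but a difference between the 2 cultures or mice, sex included, was not tested.

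For the hypoxia-responsive genes, dim spots near background are argued against as the whole cause only. The 16 members with the brighter signals had a median of 0.29, with 13 above 0. That median was below the 0.49 of all 32 members, so how far dim signal added to the size was not settled. Of the members past 2-fold, Vegfa, Egln3, Mgarp and Bhlhe40 had signals from 68.8 to 128 in c-Maf+/-. Ak4, Ddit4, Ankrd37 and Bnip3 were brighter there, from 267 to 2964. Each alternative scaling shifted differences upward, so none of them tests the scaling as a cause here. A shift shared by all genes is still argued against as the whole cause. Without the 4 genes that prompted it, the list lay at percentile 100 of matched random lists, which such a shift cannot change. Oxygen or cell density differing between the 2 cultures could give the same pattern and cannot be told apart from genotype with 1 array per genotype.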
